A study of Mus musculus with 6 samples.

How the data were processed

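Poly(A) RNA of the mouse PVH was prepared as stranded libraries with dUTP marking and adapters carrying unique molecular identifiers and was sequenced as read pairs on an Illumina instrument, per the labels' protocols. Per the submitters' processing notes, cutadapt, HISAT2 and StringTie were used; their versions and roles are not given in the sources used here, nor is whether the molecular identifiers were used to remove duplicates or whether strand was used in counting. The notes name genome build mm9, but of 35024 gene identifiers shared with the GENCODE M21 annotation of GRCm38, 32009 (91.4%) have identical start and end positions in the deposited table, so its coordinates are given as GRCm38. The deposited table lists 35148 genes with a count and an FPKM value for each of the 6 libraries. The counts are whole numbers per gene as the authors deposited them, with no normalization. The FPKM values deposited by the authors are those counts scaled by gene length and library total, and every per-sample column was matched to a library by the words and number in its name and the sample title.

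The samples fall into 2 groups of 3, AAV2-GFP and AAV2-Cre-GFP, 8 weeks after injection. All choices of test, gene lists, named genes and alternatives were made before the data were examined, except those named as later. The main test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3 on the counts, with TMM normalization and genes kept by filterByExpr at its minimum count of 10. This left 20865 genes, tested without covariates and two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The written plan put a limma fit of FPKM first unless the table held counts; since it does, that fit became an alternative. Standard errors of log2 changes come from the quasi-likelihood F statistic. Means and SDs are given in FPKM, and CPM values of single RNA kinds use the deposited totals. The common biological coefficient of variation was 27.1%. Total counts ran from 41890769 to 54702785 per library, so counting error is small for most named genes, and the spread between libraries sets the precision. No pair of libraries agreed within sampling noise: the chi-square statistic per gene, over genes with at least 20 counts in the pair, was 11.4 or more in every pair.

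Lists of genes for synapses, neuropeptides, cell types, neighbouring regions, inflammation, stress and RNA quality, 35 in all, were written in advance, and 34 had at least 4 tested members. They were tested on log2 CPM (prior count 2) with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, and were adjusted over the lists. List members were counted after adjustment over all genes and adjusted over the list alone. Gene ontology and KEGG terms of the table with 10 to 500 tested genes were tested for over-representation by one-sided Fisher's exact tests, adjusted per direction and source. Ruvbl2 was also compared by a two-sided exact permutation test of FPKM. The 31-base words shared between transcripts were counted in the GENCODE M21 transcript sequences.

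The rule for named genes took Ruvbl2 and Ruvbl1; up to 12 of the largest rises and 12 of the largest falls past the threshold with non-overlapping groups and a mean of at least 1 FPKM; up to 4 members past the threshold of each list named, or the 2 with the smallest p where none passed; 12 genes named in every case (Oxt, Avp, Crh, Trh, Sim1, Mc4r, Gria1, Grin1, Camk2a, Gfap, Aif1 and Cd68); and, where fewer than 5 genes passed in all, the 5 with the smallest p in each direction. Some list members that the rule takes are not reported here. Genes of ribosomal RNA and of other organs, and genes near named ones, were named after their values were seen.

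The tests were tested on simulated data, counts drawn from the means and library sizes of this comparison, with 20865 genes. In that simulation edgeR recovered 25.4% of genes changed 1.5-fold, 46.3% of those changed 2-fold and 66.7% of those changed 4-fold, with 9 false calls, and DESeq2 recovered 38.8%, 56.7% and 78.8% with 49 false calls. Camera called 0 of the 34 unshifted lists. A list shifted by 0.5 in log2 had a camera adjusted p of 8.33e-09 with the preset and 0.156 with an estimated correlation. The second test thus missed the 1 shift tried. The simulated genes were drawn independently of each other, so these results do not test the preset where the genes of a list vary together. In the real libraries the estimated correlation reached 0.83, for the thalamus list.

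The alternatives chosen beforehand were DESeq2 1.42.0; no filter; a robust fit; the replicate number as a block; each library left out in turn; and a limma fit of log2(FPKM + 0.5) over genes with a mean of at least 1 FPKM. That fit was repeated with pseudocounts of 0.1 and 1, no filter, a mean of at least 5 FPKM, median-ratio factors, quantile normalization, rescaling to TPM, robust moderation and array weights; its fold changes understate those of low genes. Added after seeing the data were fits without AAV2-Cre-GFP libraries 2 and 3, which hold kidney transcripts, and without these and AAV2-GFP library 1, which holds testis transcripts. Also added were fits without ribosomal RNA and other-organ genes, with the GC and length trend of each library removed by splines with 5 degrees of freedom, the same limma fit without that removal, and an adjusted p of 0.1. The fits that leave out 2 and 3 libraries compare 3 AAV2-GFP libraries with 1 and 2 with 1, so the lone AAV2-Cre-GFP library is assumed to vary like the AAV2-GFP ones. The GC content came from GENCODE M21 transcripts and the length from the ratio of counts to FPKM, for 99.8% of tested genes. A sex term was not fitted, since sex-linked genes did not show both sexes within a group or between the groups. Xist stood between 592 and 725 CPM and the Y-linked gene Ddx3y at most at 0.421 CPM in every library, the female pattern in each. Reads were not used here, so Cre, GFP and single exons of Ruvbl2 were not analysed here.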

Results

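RNA of the paraventricular nucleus of the hypothalamus (PVH), a small group of neurosecretory and pre-autonomic neurons that control feeding, stress hormones and water balance, was sequenced from mice with loxP-flanked Ruvbl2 alleles. The animals had received an injection of an adeno-associated virus of serotype 2 into the PVH. In 3 samples the virus carried GFP alone (AAV2-GFP) and in 3 it carried Cre recombinase with GFP (AAV2-Cre-GFP), and tissue was taken 8 weeks later. Cre removes the floxed part of Ruvbl2, which encodes an ATPase found in chromatin remodelling and chaperone complexes. According to the series description, the comparison asks what RUVBL2 does in the regulation of synaptic plasticity. Total counts were 43738694, 42003794 and 49414012 in the AAV2-GFP libraries 1 to 3 and 41890769, 45119184 and 54702785 in the AAV2-Cre-GFP libraries 1 to 3. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples.

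Ruvbl2 itself, the targeted gene, was not lower in the libraries labelled AAV2-Cre-GFP. Its level was 8.66 ± 1.27 FPKM (SD, n = 3) in the AAV2-GFP libraries and 9.38 ± 0.240 FPKM (SD, n = 3) in those labelled AAV2-Cre-GFP. Single libraries held 9.90, 7.36 and 8.72 FPKM with AAV2-GFP and 9.53, 9.10 and 9.51 FPKM with AAV2-Cre-GFP, from 1032 to 1755 counts each. The log2 difference was 0.077 ± 0.11 (SE) with a 95% interval of -0.18 to 0.33, so the largest fall inside the interval is 11.7% (edgeR adjusted p = 0.773). Without AAV2-GFP library 1 it was 0.18 and without AAV2-GFP library 2 it was -0.029. A two-sided exact permutation test of the FPKM values gave p = 0.5, where 3 libraries against 3 cannot go below 0.1. The gene (ENSMUSG00000003868) lies on the minus strand of chromosome 7 at 45421760 to 45438096 (GRCm38). Genes on the plus strand overlap both of its ends, Gys1 (45434844 to 45456619) the 5' part and AC151602 (45418353 to 45421854) the 3' end. The value counts reads over the whole gene, so it does not separate deleted from retained exons. Ruvbl1, which encodes the partner ATPase, stood at 12.7 ± 1.04 and 14.7 ± 1.21 FPKM (SD, n = 3; edgeR adjusted p = 0.405). Because the targeted gene did not separate the groups, the libraries are called GFP-labelled and Cre-labelled from here on, and every direction below compares libraries so labelled.

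Of 20865 genes tested, 2 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and both were lower in the Cre-labelled libraries. Hnrnpa3, which encodes an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein family, fell from 25.1 ± 1.32 to 1.01 ± 0.198 FPKM (SD, n = 3), a 25.3-fold difference with a log2 change of -4.66 ± 0.14 (SE; edgeR adjusted p = 1.73e-05). Pcsk1n, which encodes proSAAS, an inhibitor of a prohormone convertase, fell from 181 ± 8.96 to 121 ± 5.18 FPKM (SD, n = 3), a log2 change of -0.62 ± 0.056 (SE; edgeR adjusted p = 0.0495). Hnrnpa3 (ENSMUSG00000059005) lies on the plus strand of chromosome 2 at 75659261 to 75669407 and Pcsk1n (ENSMUSG00000039278) on the plus strand of chromosome X at 7919822 to 7924410 (GRCm38). In each of the Cre-labelled libraries both genes were below every GFP-labelled library. The Hnrnpa3 value is uncertain, since 29 genes in the table, most of them processed pseudogenes, share at least 20% of their 31-base words with its transcripts. The summed level of these copies was 259.9 normalised counts (CPM, scaled to the library total) in the GFP-labelled and 244 CPM in the Cre-labelled libraries, so it did not move with Hnrnpa3. Whether reads were assigned differently between Hnrnpa3 and its copies was not tested. The 25.3-fold difference therefore holds for the deposited counts of this gene model and may not be one of the transcript. The Pcsk1n call was lost without AAV2-GFP library 1, 2 or 3 (edgeR adjusted p = 0.0671, 0.301 and 0.143) and without AAV2-Cre-GFP library 2 or 3 (edgeR adjusted p = 0.20 and 0.175), with log2 changes between -0.65 and -0.58. No gene passed as higher. At an unadjusted p under 0.05 there were 1692 higher and 1901 lower genes, 17.2% of those tested, and the 2 groups did not overlap for 22.8% of genes, where chance gives 10%. The count depended on the test: DESeq2 called 1322 genes, 514 higher and 808 lower, and without AAV2-Cre-GFP library 1 edgeR called 296, 245 of them higher.

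**Figure D1:**
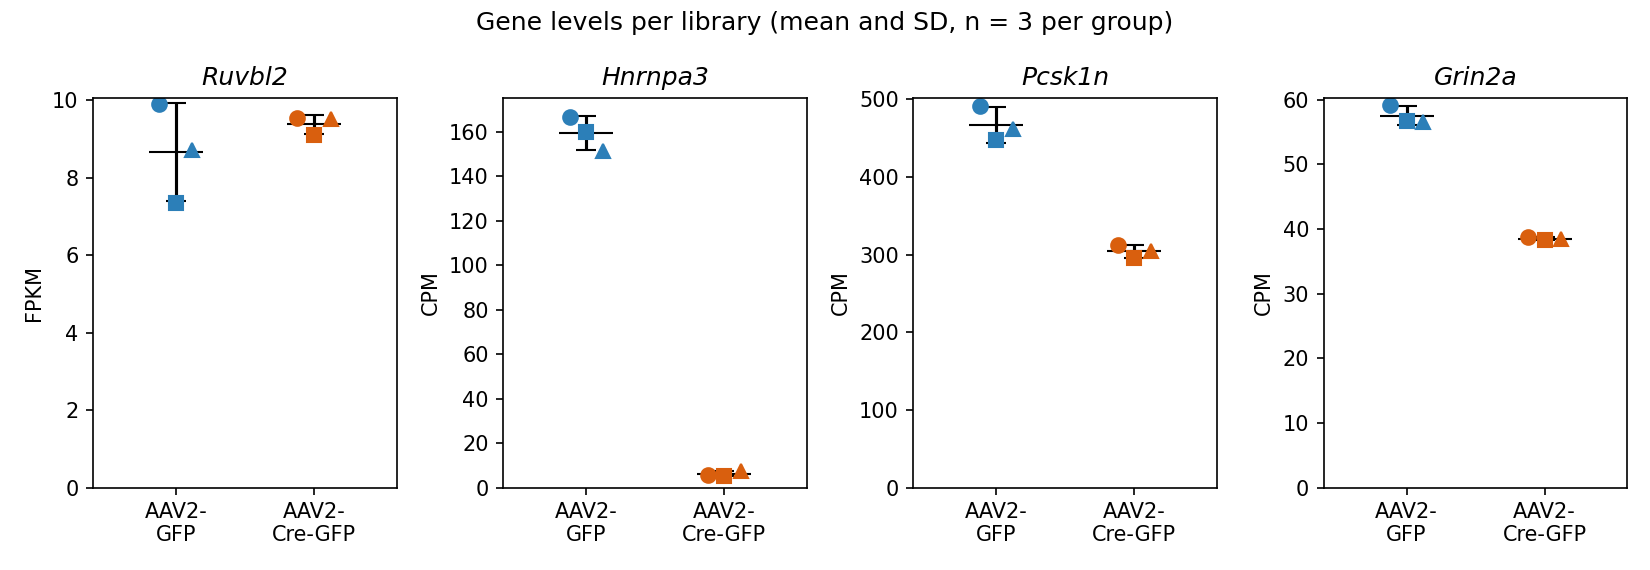
Levels of 4 genes in each library: Ruvbl2 in FPKM and Hnrnpa3, Pcsk1n and Grin2a in normalised counts (CPM; vertical axes from 0). Circles, squares and triangles are libraries 1, 2 and 3 of a group, and bars give the mean and SD of the 3 libraries; Ruvbl2 overlaps between the groups while Hnrnpa3 fell from 25.1 to 1.01 FPKM on average.

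The 8 further genes among the 5 with the smallest p in each direction did not pass the threshold. On the lower side were Grin2a, the GluN2A subunit of the NMDA receptor, at 2.73 ± 0.0777 against 1.87 ± 0.0408 FPKM (SD, n = 3), Rab11fip5, a Rab11 effector of endosomal recycling, at 19.9 ± 0.611 against 14.2 ± 0.476 FPKM, and Slc9a7, a sodium-proton exchanger of the trans-Golgi network, at 5.43 ± 0.387 against 2.54 ± 0.350 FPKM. Each of these 3 had an edgeR adjusted p of 0.0514. On the higher side were Xntrpc at 0.716 ± 0.0841 against 2.13 ± 0.153 FPKM, Smpdl3a, an acid sphingomyelinase-like phosphodiesterase, at 5.97 ± 0.10 against 10.6 ± 0.402 FPKM, and Cd24a, a surface glycoprotein, at 14.4 ± 0.218 against 22.2 ± 1.74 FPKM (SD, n = 3), with edgeR adjusted p of 0.0514, 0.0514 and 0.0592. Xntrpc spans the gene models Xndc1 and Trpc2 on the same strand, so its reads can be assigned to more than 1 model. The other 2 genes on this side were the ribosomal RNA model CT010467 (edgeR adjusted p = 0.0514) and Gm10800 (edgeR adjusted p = 0.0525). Gm10800 had no count in any GFP-labelled library and 60, 77 and 73 counts in the Cre-labelled ones, at least 67.2-fold higher against a floor of 3 counts over the GFP-labelled group. Other tested genes with counts only in the Cre-labelled libraries included Gbp8, Tmem40 and C1rb, named after their values were seen. No tested gene had counts only in the GFP-labelled libraries, and the cause of this one-sided pattern was not tested.

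CT010467 stood at 2219, 2201 and 2072 CPM in the GFP-labelled libraries 1 to 3 and at 17633, 13492 and 7301 CPM in the Cre-labelled libraries 1 to 3. A further 4 genes were picked out after their values were seen. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, stood at 88.1 ± 5.73 and 292 ± 121 CPM (SD, n = 3). Its level was 414, 290 and 171 CPM in the Cre-labelled libraries 1 to 3. Rn7sk, the 7SK small nuclear RNA, stood at 1.94 ± 0.409 and 6.72 ± 3.37 CPM, and mt-Rnr2, the large mitochondrial ribosomal RNA, at 1996 ± 143 and 2657 ± 453 CPM (SD, n = 3). For each of CT010467, Lars2, Rn7sk and mt-Rnr2 every Cre-labelled library lay above every GFP-labelled one. Among the Cre-labelled libraries each of these was highest in library 1 and lowest in library 3, so Lars2 followed the ribosomal RNA model. The small mitochondrial ribosomal RNA, mt-Rnr1, stood at 1223 ± 148 and 1576 ± 279 CPM (SD, n = 3), and its level in GFP-labelled library 1 (1390.3 CPM) was above that in Cre-labelled library 3 (1287 CPM). Transcripts of other organs were present in single libraries. A list of 30 kidney genes summed to 372 and 395 CPM in the Cre-labelled libraries 2 and 3 and to between 46.7 and 65.8 CPM in the other 4. A list of 26 testis genes summed to 411 CPM in GFP-labelled library 1 and to at most 16.5 CPM elsewhere. A list of 20 skeletal muscle genes summed to 275 CPM in Cre-labelled library 3 and to at most 91.0 CPM elsewhere, while the liver list ranged from 52.1 to 71.2 CPM. These 4 lists were written after the other-organ transcripts had been seen, and 1 of the kidney genes, Slc22a6, is also in the list of mural genes fixed in advance. The pituitary hormone genes Gh and Prl stood at 13.3 and 16.5 CPM in GFP-labelled library 2 and at most at 0.955 and 2.27 CPM elsewhere. Without GFP-labelled library 1 and Cre-labelled libraries 2 and 3, a setting also chosen after seeing the data, edgeR called 1059 genes, 273 higher and 786 lower, from 2 libraries against 1.

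**Figure D2:**
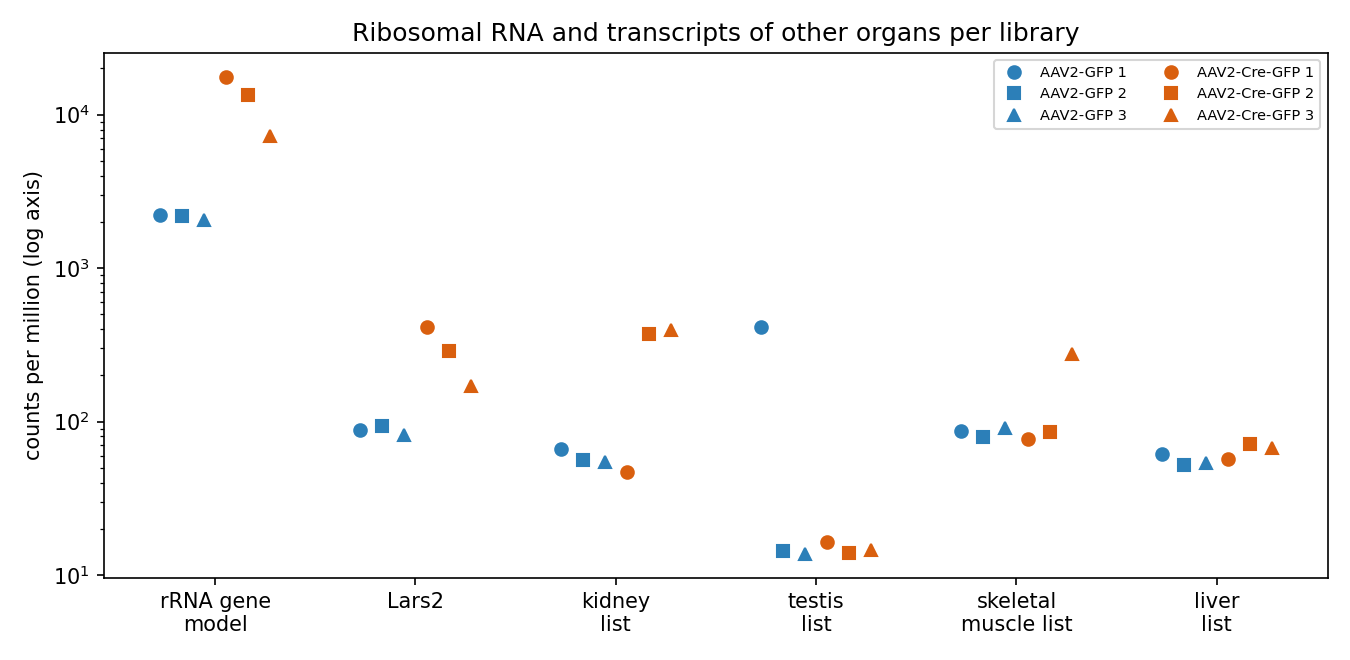
CPM (log axis) of the ribosomal RNA model CT010467, Lars2 and the summed kidney, testis, skeletal muscle and liver lists in each of the 6 libraries. Blue symbols are GFP-labelled and orange symbols Cre-labelled libraries; CT010467 separates the labels, and kidney transcripts reach 372 and 395 CPM in Cre-labelled libraries 2 and 3.

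Genes of neurons and their synapses were lower as groups in the Cre-labelled libraries, each by a small amount. All 40 tested genes of presynaptic release and all 24 pan-neuronal genes were lower, with median log2 differences of -0.19 and -0.21. Of the voltage-gated ion channels 36 of 39 were lower (median -0.22), of the excitatory synapse genes 41 of 48 (median -0.17) and of the inhibitory synapse genes 19 of 26 (median -0.13). Their camera adjusted p were 3.02e-09, 3.11e-09, 6.43e-09, 2.61e-06 and 0.00675 with the preset correlation. With an estimated correlation the adjusted p were 0.267, 0.282, 0.174, 0.224 and 0.364, so none of these calls held. By fry, which does not compare a list with other genes, the adjusted p were 0.0293, 0.0293, 0.0250, 0.0293 and 0.0430. In each of the 5 lists every Cre-labelled library lay below every GFP-labelled library, although for the inhibitory list the nearest mean scores were -0.0790 and -0.0796. None of these genes passed in edgeR when adjusted over all genes, whereas DESeq2 called some of them, with adjusted p of 1.44e-08 for Syn1, 6.98e-10 for Grin2a, 8.16e-09 for Gabrb1 and 8.15e-06 for Rbfox3. In edgeR, adjusted over the list alone, 14 presynaptic, 12 pan-neuronal, 16 ion channel, 15 excitatory and 3 inhibitory genes were lower and 1 excitatory gene was higher. Levels of CT010467, Rn7sk and mt-Rnr2 were higher in the same 3 libraries. The excitatory median was -0.11 without Cre-labelled library 1 (camera adjusted p = 0.000147), and the inhibitory call was lost in the FPKM fit with limma after quantile normalization (0.0776, median -0.088). Without Cre-labelled libraries 2 and 3, which leaves 3 libraries against 1, the medians of these 5 lists were -0.24, -0.31, -0.24, -0.20 and -0.11, and the inhibitory list was not called (camera adjusted p = 0.10; 0.0883 when GFP-labelled library 1 was also left out).

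Among the members of these lists with the smallest p were Syn1, the vesicle phosphoprotein synapsin I, at 126 ± 12.6 against 84.8 ± 7.21 FPKM, and Nptxr, the neuronal pentraxin receptor, at 77.7 ± 4.21 against 54.0 ± 5.46 FPKM (SD, n = 3). Among pan-neuronal genes, Rbfox3, the nuclear marker NeuN, stood at 17.3 ± 0.481 against 14.0 ± 0.123 FPKM. The potassium channel genes Kcnb2 and Kcnd3 had log2 differences of -0.61 ± 0.12 and -0.37 ± 0.071 (SE). Of the excitatory genes, Grin2b, the GluN2B subunit, stood at 10.7 ± 0.302 against 8.51 ± 0.469 FPKM beside Grin2a. The GABA-A receptor genes Gabrb1 and Gabrb2 had log2 differences of -0.44 ± 0.063 and -0.85 ± 0.14 (SE). Of 3 further genes fixed in advance, Gria1, an AMPA receptor subunit, differed by -0.078 ± 0.056, Grin1, the obligatory NMDA receptor subunit, by -0.18 ± 0.071, and Camk2a, a kinase of the postsynaptic density, by -0.15 ± 0.091 (SE). Gria1 was at -0.021 without Cre-labelled library 2, and Camk2a and Grin1 were at -0.043 and -0.11 without Cre-labelled library 1. None of the genes in this paragraph passed in edgeR, with adjusted p between 0.0514 and 0.528.

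The list of PVH neuropeptides and identity factors was lower as a group, with 21 of 25 genes lower and a median log2 difference of -0.39 (camera adjusted p = 8.83e-05; adjusted p = 0.392 with an estimated correlation). Crh, the corticotropin-releasing hormone, stood at 7.56 ± 1.51 against 4.27 ± 0.627 FPKM (SD, n = 3; edgeR adjusted p = 0.104) and Vgf, a neuropeptide precursor, at 72.6 ± 5.92 against 52.5 ± 6.33 FPKM (edgeR adjusted p = 0.0793); these 2 passed when adjusted over the list alone. Oxytocin and vasopressin varied widely inside each group: Oxt stood at 447 ± 227 against 207 ± 196 FPKM and Avp at 138 ± 70.7 against 79.8 ± 50.6 FPKM (edgeR adjusted p = 0.454 and 0.457). With 1 library left out the log2 difference of Oxt ran from -2.22 (without Cre-labelled library 3) to -0.68 (without Cre-labelled library 1), and that of Avp from -1.47 (without Cre-labelled library 3) to -0.54 (without GFP-labelled library 3). Trh, the thyrotropin-releasing hormone, differed by -0.17 ± 0.22 and Sim1, a transcription factor that specifies PVH neurons, by -0.70 ± 0.28 in log2 (SE; edgeR adjusted p = 0.753 and 0.256). Trh was at -0.40 without GFP-labelled library 1 and turned to 0.039 without GFP-labelled library 3. Only 2 of the 3 Cre-labelled libraries lay below every GFP-labelled library in this list, while CT010467 was higher in all 3. Without GFP-labelled library 1 and Cre-labelled libraries 2 and 3, with 2 libraries against 1, the median of the list was -0.62. Receptors of energy balance were lower as a group by a median of -0.11, with 18 of 25 genes lower and none past the list alone (camera adjusted p = 0.0197; adjusted p = 0.494 with an estimated correlation). That call was lost without GFP-labelled library 2 or 3 or Cre-labelled library 2 (camera adjusted p = 0.129, 0.113 and 0.0767), and the median ran from -0.21 without GFP-labelled library 1 to -0.066 without GFP-labelled library 3; in the FPKM fit with limma it was -0.052 (camera adjusted p = 0.0599). Oprm1, the mu opioid receptor, and Igf1r, the receptor of insulin-like growth factor, led it with log2 differences of -0.77 ± 0.24 and -0.18 ± 0.066, and Mc4r, the melanocortin receptor of the PVH, differed by -0.45 ± 0.22 (SE; edgeR adjusted p = 0.356).

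Thalamic marker genes, a list for neighbouring tissue taken with the dissection, were lower in 15 of 16 cases, with a median of -0.29 (camera adjusted p = 0.0299; adjusted p = 0.669 with an estimated correlation), but their scores spread widely within both groups. The call was lost without GFP-labelled library 1 or 2 or Cre-labelled library 1, with medians of -0.031, -0.28 and -0.087 (camera adjusted p = 0.466, 0.0637 and 0.657). Without GFP-labelled library 3 or Cre-labelled library 2 the medians were -0.44 and -0.47 (camera adjusted p = 0.00122 and 0.000760), and with Cre-labelled library 1 alone against the 3 GFP-labelled libraries the median was -0.86. Calb2 and Cbln1 led this list with log2 differences of -0.37 ± 0.14 and -0.31 ± 0.12 (SE); Calb2 was at -0.22 without Cre-labelled library 1 and Cbln1 at -0.18 without GFP-labelled library 1. Markers of other hypothalamic nuclei gave no call, with 13 of 23 higher and a median of 0.054 (camera adjusted p = 0.510). Their median ran from 0.25 without GFP-labelled library 1 to -0.078 without GFP-labelled library 3, and without Cre-labelled library 2 the list was called at 0.13 (camera adjusted p = 0.0444). With Cre-labelled library 1 alone, the median was 0.18 against the 3 GFP-labelled libraries and 0.35 against libraries 2 and 3 (camera adjusted p = 0.0258 and 0.0418), and in the FPKM fit with limma it was -0.052 (0.582). Hmx2 and Pomc led them with log2 differences of 1.48 ± 0.41 and 2.25 ± 0.69 (SE). Pomc stood at 28.4, 3.32 and 17.9 TMM-normalised CPM in Cre-labelled libraries 1 to 3, against 1.90 to 4.85 in the GFP-labelled ones. Cre-labelled library 2 thus lay inside the GFP-labelled range for Pomc. Hmx2 lay near the floor, at 0.0878 ± 0.0128 against 0.258 ± 0.0772 FPKM (SD, n = 3).

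All 21 tested genes of cholesterol synthesis were lower in the Cre-labelled libraries, with a median log2 difference of -0.31, and each Cre-labelled library lay below every GFP-labelled one. The camera adjusted p was 8.54e-10; with an estimated correlation of the list's genes the adjusted p was 0.282. Adjusted over the list alone, 14 were lower. Stard4, a sterol transfer protein, stood at 7.94 ± 0.836 against 5.83 ± 0.131 FPKM (SD, n = 3; edgeR adjusted p = 0.0731). CT010467 was higher in the same libraries. With 1 library left out, the median lay between -0.36 and -0.24.

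Immune and glial response genes were higher as groups. Every Cre-labelled library lay above every GFP-labelled one for the interferon, complement, homeostatic microglia and reactive astrocyte lists and for CT010467, but only Cre-labelled libraries 2 and 3 did so for antigen presentation, activated microglia and lymphocyte genes. Of the interferon response genes 29 of 32 were higher, with a median log2 difference of 0.51 (camera adjusted p = 1.91e-08; adjusted p = 0.286 with an estimated correlation), and 6 were higher when adjusted over the list alone. Ifit3 stood at 6.26 ± 0.939 against 10.6 ± 1.13 FPKM and Isg15 at 1.23 ± 0.256 against 3.05 ± 0.476 FPKM (SD, n = 3; edgeR adjusted p = 0.0793 and 0.111). The interferon median was 0.31 without Cre-labelled library 2 (camera adjusted p = 1.13e-06). In the FPKM fit with limma it was 0.27 (camera adjusted p = 0.000308), and over genes with a mean of at least 5 FPKM it was 0.24 and the call was lost (0.0918). In the fits that keep only Cre-labelled library 1 it was 0.30 against 3 GFP-labelled libraries and 0.17 against the 2 without testis transcripts. Complement genes were higher in 16 of 18 cases by a median of 0.32, none past the list alone (camera adjusted p = 0.000187; adjusted p = 0.174 with an estimated correlation); Cfp, properdin, and Cfb, factor B, led them with log2 differences of 0.50 ± 0.12 and 1.04 ± 0.29 (SE). Cfb stood at 5.73 TMM-normalised CPM in Cre-labelled library 1 and at 11.7 and 12.7 in libraries 2 and 3, against 4.85 to 4.91 in the GFP-labelled ones. The complement call was lost in the FPKM fit with limma over genes with a mean of at least 5 FPKM (camera adjusted p = 0.0698, median 0.17). Homeostatic microglia genes were higher in 17 of 23 cases by a median of 0.17, 1 past the list alone (camera adjusted p = 0.00136; adjusted p = 0.282 with an estimated correlation). Tyrobp and Fcer1g, signalling adaptors of microglia, led them with log2 differences of 0.79 ± 0.16 and 0.52 ± 0.17, whereas Aif1, the marker IBA1, stood at 3.58 ± 3.31 against 1.97 ± 0.380 FPKM and its log2 difference turned from -0.89 to 0.20 without GFP-labelled library 1.

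Further inflammatory lists were higher as groups. Reactive astrocyte genes were higher in 22 of 26 cases by a median of 0.29 (camera adjusted p = 0.000972; adjusted p = 0.174 with an estimated correlation), antigen presentation genes in 18 of 22 by 0.29 (0.00237; adjusted p = 0.428 with an estimated correlation) and activated microglia and phagocyte genes in 19 of 27 by 0.28 (0.00511; adjusted p = 0.468 with an estimated correlation). Adjusted over the list alone, 1, 3 and 3 of them were higher. Without Cre-labelled libraries 2 and 3, which hold kidney transcripts, 3 libraries stand against 1 and only the GFP-labelled ones give the spread; the medians were then 0.22, 0.10 and 0.056, without a call (camera adjusted p = 0.193, 0.443 and 0.546). The activated microglia list lost its call without Cre-labelled library 3 (camera adjusted p = 0.0555, median 0.24), and its medians without GFP-labelled libraries 1 and 3 were 0.18 and 0.13. Among astrocyte genes, Tm4sf1 and Vim had log2 differences of 0.63 ± 0.14 and 0.39 ± 0.10 (SE), and Gfap, the astrocytic filament protein, stood at 53.7 ± 5.68 against 66.0 ± 13.7 FPKM (SD, n = 3; edgeR adjusted p = 0.381). Its log2 difference was 0.26, and 0.099 without Cre-labelled library 1. H2-K1, a class I histocompatibility gene, stood at 11.4 ± 0.551 against 15.0 ± 0.390 FPKM and H2-Aa, of class II, at 0.512 ± 0.144 against 1.64 ± 0.768 FPKM. Spp1, osteopontin, which kidney also expresses, stood at 3.09 ± 0.197 against 29.9 ± 17.1 FPKM, Cd9 at 15.3 ± 1.03 against 20.3 ± 1.86 FPKM, and the lysosomal marker Cd68 at 5.02 ± 0.438 against 6.26 ± 0.587 FPKM (SD, n = 3). The edgeR adjusted p of these 8 genes lay between 0.0705 and 0.405. Lymphocyte genes were higher in 16 of 18 cases by a median of 0.57 (camera adjusted p = 0.0112; adjusted p = 0.468 with an estimated correlation), a call lost without GFP-labelled library 3 (0.0690) and without Cre-labelled library 2 (0.0767). It was also lost in the FPKM fit with limma, where the median was 0.18 (camera adjusted p = 0.926), and after quantile normalization (0.17, 0.782). Their median was 0.99 without Cre-labelled library 1, 0.36 without Cre-labelled library 2 and -0.25 without both kidney libraries, which leaves 3 libraries against 1. Ccl5 and Gzmk led them with log2 differences of 1.94 ± 0.53 and 1.18 ± 0.41 (SE). Both lay near the floor, at 0.137 ± 0.0252 against 0.576 ± 0.201 FPKM and 0.248 ± 0.0188 against 0.597 ± 0.201 FPKM (SD, n = 3).

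**Figure D3:**
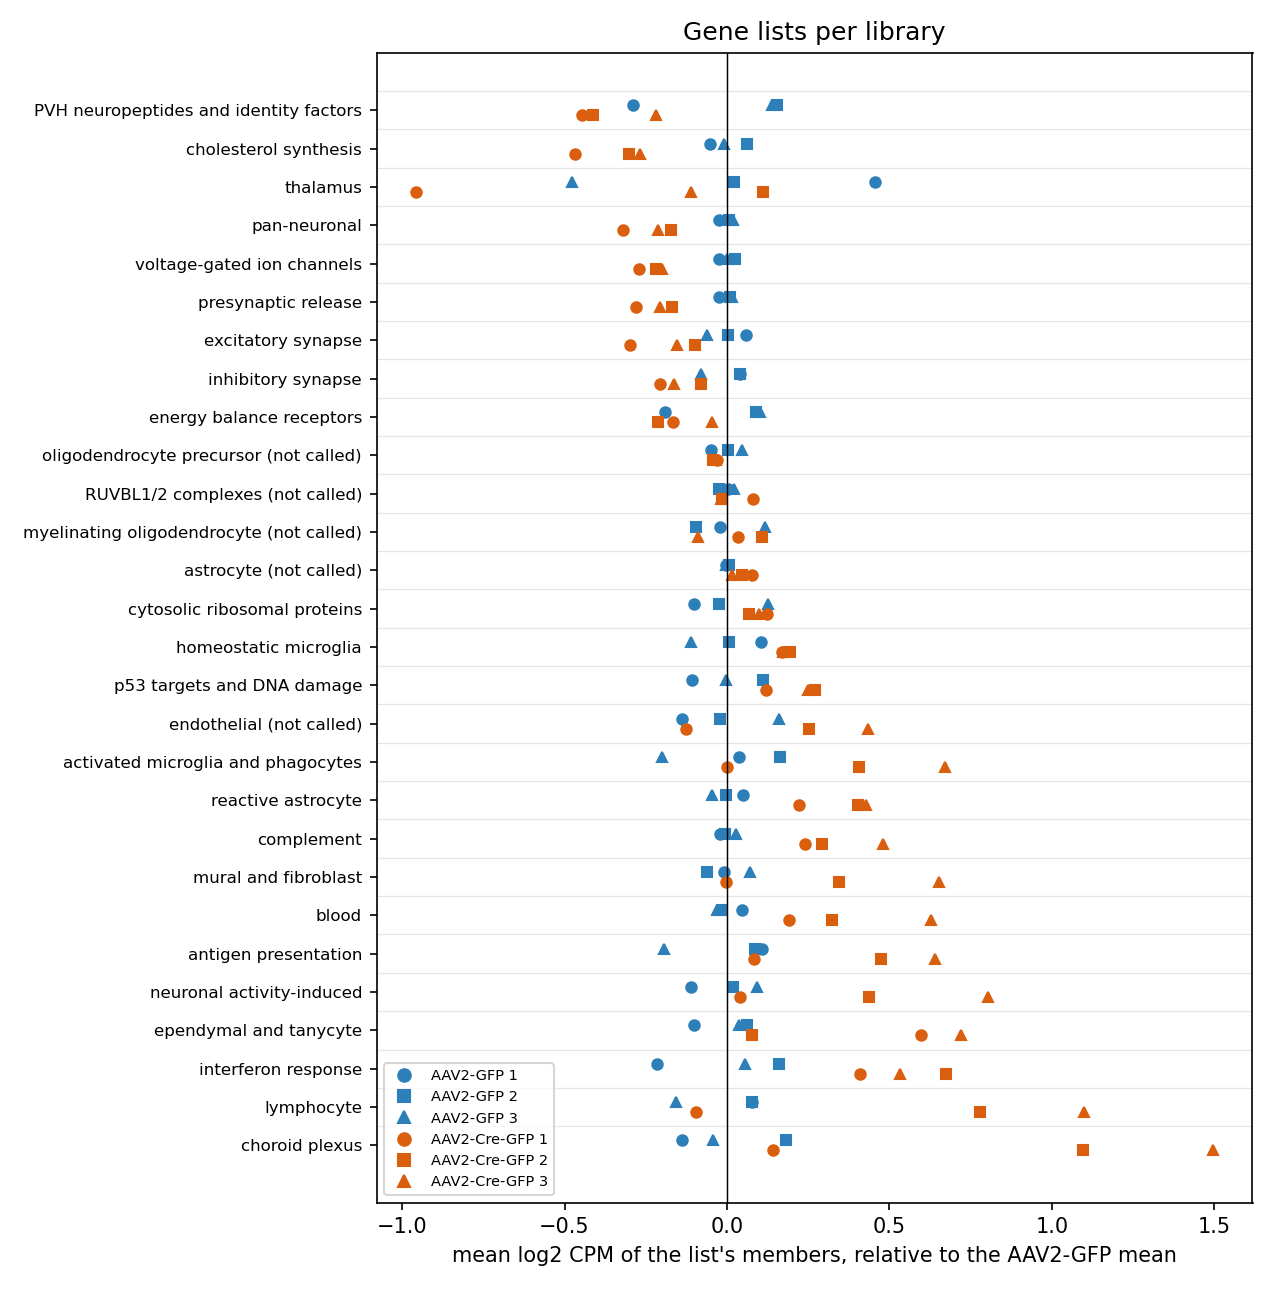
Mean log2 CPM of the members of each called list and of 5 lists that were not called, per library and relative to the mean of the GFP-labelled libraries (horizontal axis, log2 units). Blue symbols are GFP-labelled and orange symbols Cre-labelled libraries 1 (circle), 2 (square) and 3 (triangle); the pan-neuronal and presynaptic lists separate the labels, while the choroid plexus and lymphocyte lists are high only in Cre-labelled libraries 2 and 3.

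Ependymal and tanycyte genes, of the cells that line the third ventricle, were higher in 16 of 17 cases by a median of 0.46 (camera adjusted p = 8.83e-05; adjusted p = 0.296 with an estimated correlation), 3 of them past the list alone. Their mean scores relative to the GFP-labelled mean were 0.60 and 0.72 in Cre-labelled libraries 1 and 3 but 0.076 in library 2, close to 0.062 in GFP-labelled library 2. Ak7 and Foxj1, both genes of motile cilia, stood at 6.77 ± 0.589 against 11.2 ± 1.09 FPKM and 12.4 ± 1.36 against 18.4 ± 2.10 FPKM (SD, n = 3; edgeR adjusted p = 0.0705 and 0.0855). Astrocyte, myelinating oligodendrocyte, oligodendrocyte precursor and endothelial lists gave no call, with medians of 0.058, -0.031, -0.086 and 0.066 (camera adjusted p = 0.462, 0.961, 0.408 and 0.0721), although 3 endothelial genes were higher when adjusted over the list alone. The endothelial list passed in 14 of 25 refits, with medians of 0.20 without Cre-labelled library 1 and 0.22 without GFP-labelled library 3 (camera adjusted p = 0.000623 and 0.00947), and had medians of 0.014 without GFP-labelled library 1, -0.00098 without Cre-labelled library 3 and -0.12 without both kidney libraries. The oligodendrocyte median and mean differ in sign (-0.031 and 0.022). The astrocyte list was divided: adjusted over the list alone 2 genes were higher and 2 lower, and S100b and Cldn10 led it with log2 differences of 0.46 ± 0.072 and 0.46 ± 0.090 (SE). In the other 3 lists the smallest p belonged to Mal and Enpp6, with log2 differences of 0.26 ± 0.073 and 0.79 ± 0.35, to Gpr17 and Tnr, with 0.29 ± 0.11 and -0.19 ± 0.078, and to Slc2a1 and Ly6a, with 0.31 ± 0.083 and 1.34 ± 0.36 (SE). Tnr was at -0.11 without GFP-labelled library 3, and Enpp6 was at 0.49 without Cre-labelled library 3 and turned to -0.12 without both kidney libraries. Blood genes were higher in 7 of 8 cases by a median of 0.38, with 4 past the list alone (camera adjusted p = 0.00511; adjusted p = 0.282 with an estimated correlation). The beta-globin genes Hbb-bs and Hbb-bt stood at 52.1 ± 7.19 against 104 ± 18.1 FPKM and 24.7 ± 2.94 against 43.9 ± 7.34 FPKM (SD, n = 3), and the list's median was 0.24 without Cre-labelled library 3 (camera adjusted p = 0.0231).

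Genes of the RUVBL1/2 complexes, which include the INO80, SRCAP and TIP60 remodellers and the R2TP chaperone with its kinase clients, gave no call: 21 were higher and 19 lower, with a median log2 difference of 0.013 (camera adjusted p = 0.799; adjusted p = 0.923 with an estimated correlation). With Cre-labelled library 1 alone against the 3 GFP-labelled libraries their median was 0.096 (camera adjusted p = 0.0417). Ino80, the remodeller ATPase, and Tti2, a chaperone of large kinases, had the smallest p, with log2 differences of 0.30 ± 0.081 and 0.29 ± 0.12 (SE; edgeR adjusted p = 0.138 and 0.257), and Tti2 was at 0.19 without Cre-labelled library 1. Of the p53 target and DNA damage genes 19 of 28 were higher by a median of 0.075, with 4 higher and 1 lower past the list alone (camera adjusted p = 0.0293; adjusted p = 0.428 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, stood at 1.65 ± 0.00799 against 3.19 ± 0.401 FPKM and Ccng1, cyclin G1, at 10.4 ± 0.615 against 14.2 ± 0.420 FPKM (SD, n = 3; edgeR adjusted p = 0.0705 each). This call was lost without GFP-labelled library 1 (camera adjusted p = 0.395, median 0.023) and without Cre-labelled library 2 (0.0624, median 0.094), and the median was 0.15 without GFP-labelled library 2 and 0.063 in the FPKM fit with limma (0.0527). Neuronal activity-induced genes were higher in 21 of 24 cases by a median of 0.41, 1 past the list alone (camera adjusted p = 0.00153; adjusted p = 0.464 with an estimated correlation), and lost the call without Cre-labelled library 3 (0.109, median 0.25). Without both kidney libraries, with 3 libraries against 1, their median was -0.049 (camera adjusted p = 0.955). Junb and Npas4 led them with log2 differences of 1.16 ± 0.23 and 0.43 ± 0.11 (SE). Of 803 genes in the tested lists, edgeR called 0 when adjusted over all genes, 256 had an unadjusted p under 0.05 and DESeq2 called 143.

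In all, camera called 23 of 34 lists with the preset correlation, 9 lower and 14 higher, and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. By fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 10 lists passed. They were presynaptic release, pan-neuronal, voltage-gated ion channels, excitatory and inhibitory synapse, cholesterol synthesis, complement, reactive astrocyte, homeostatic microglia and blood. Over-representation of annotation terms could be tested only for the 2 lower genes, and none of 3814 gene ontology terms or 307 KEGG pathways passed.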

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

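The number of genes past the threshold depended strongly on the processing. The value of Ruvbl2 and the number of lists called with the preset correlation did so less. The list count did depend on the list test, with 23 called at the preset and 0 at an estimated correlation. Against 2 genes in edgeR, there was 1 with no filter, 22 with the robust fit, 1322 with DESeq2 and 1 with a log2 fold change of at least 1. The FPKM fit with limma gave 2, with 15 at pseudocount 0.1, 1 with no filter, 190 at a mean FPKM of at least 5, 16 with robust eBayes and 464 with array weights. Leaving out 1 library gave between 1 and 296 genes, the highest without AAV2-Cre-GFP library 1, where 245 were higher; the other 5 gave at most 4. Chosen after seeing the data, fits gave 1059 genes without the libraries with testis, kidney or muscle transcripts (AAV2-GFP library 1 and AAV2-Cre-GFP libraries 2 and 3), 4 without those with kidney transcripts (AAV2-Cre-GFP libraries 2 and 3), 8 without ribosomal RNA and other-organ genes, 35 with the GC and length trend removed (14 in the same limma fit without that removal) and 396 at an adjusted p under 0.1 (143 higher, 253 lower). Hnrnpa3 passed in all 25 refits, with adjusted p up to 0.0093, and Pcsk1n in 12, with adjusted p up to 0.405. With the replicate block 3 genes passed, all lower, 1 of them shared with the main test, and 24 lists were called. Same-numbered libraries deviated from their group means with correlations of -0.0435, 0.0121 and -0.0216, so no pairing by number was seen. These 3 values cannot exclude a pairing, since other-organ transcripts in single libraries enter the deviations. Ruvbl2 stayed outside the threshold in all 25 refits, and its log2 difference ran from -0.029 to 0.18 with 1 library left out, negative only without AAV2-GFP library 2.

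Between 19 and 24 lists were called with 1 library left out, and 14 of the 23 calls held in each of these 6 fits. Without the libraries with kidney transcripts 15 lists were called, and without those with testis, kidney or muscle transcripts 14, in fits where the lone AAV2-Cre-GFP library is assumed to vary like the AAV2-GFP ones. With the preset correlation 11 of the 23 calls held in each alternative chosen beforehand. Of these, cholesterol synthesis, ependymal, excitatory synapse, homeostatic microglia, pan-neuronal, presynaptic release, PVH neuropeptides and voltage-gated channels (8 lists) were also called in each fit added later, those with 1 AAV2-Cre-GFP library included. With an estimated correlation, run on the main comparison, 0 of the 34 lists were called. Some directions turned. Without the libraries with testis, kidney or muscle transcripts the median log2 was -0.31 for infiltrating myeloid, -0.078 for mural, -0.19 for lymphocyte, -0.24 for endothelial and -0.043 for mitochondrial genes, and 0.020 for activity-induced genes, where camera's direction turned. Without the kidney libraries it was -0.36, -0.055, -0.25, -0.12, -0.055 and -0.049 for these lists in the same order. It was also -0.044 for mural genes at a mean FPKM of at least 5, -0.15 for mitochondrial genes with quantile normalization and -0.037 for oxidative phosphorylation genes with the GC and length trend removed. Medians of cell division, neighbouring nuclei, oligodendrocyte, endoplasmic reticulum stress and RUVBL1/2 genes, not called in the main comparison, took both signs over the refits. The cause was not tested, beyond the fewer libraries or genes of each fit. A sex term was not fitted, since Xist and Ddx3y showed the same sex in every library. Ruvbl2 rests on at least 1032 counts per library, so depth does not limit it.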

Other observations

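The tests of a smaller share of neurons, of library quality and of the part of Ruvbl2 or of cells recombined, and the fits without the libraries with testis, kidney or muscle transcripts or with the GC and length trend removed, were chosen only after the results were seen. Further lists describe the tissue. Choroid plexus genes were higher in 11 of 14 cases with a median log2 difference of 0.81, 4 past the list alone (camera adjusted p = 0.00569; adjusted p = 0.428 with an estimated correlation), but Cre-labelled library 1 did not lie above the GFP-labelled ones, and the call was lost without Cre-labelled library 3 (camera adjusted p = 0.0534) and in the FPKM fit with limma (0.0599, median 0.54). Without both kidney libraries, with 3 libraries against 1, the median was 0.18 (camera adjusted p = 0.648). Its leading genes Calml4 and Tmem72 had log2 differences of 1.39 ± 0.25 and 2.66 ± 0.64 (SE). Aqp1, also in the list, stood at 1.41 CPM in Cre-labelled library 1 and at 19.9 and 23.1 CPM in libraries 2 and 3, against at most 3.19 CPM in the GFP-labelled ones. Ttr, another member, reached at most 8.35 CPM in any library. Whether these reads came from choroid plexus or from kidney was not tested. Mural and fibroblast genes were higher in 17 of 20 cases by 0.33, 1 past the list alone (camera adjusted p = 0.0145; adjusted p = 0.561 with an estimated correlation), a call lost without GFP-labelled library 1 (0.0599) or Cre-labelled library 3 (0.410, median 0.15); Dcn, decorin, and Slc22a6, a transporter that is also in the kidney list, led them with 0.58 ± 0.13 and 2.36 ± 0.78 (SE). Without both kidney libraries, Slc22a6 turned to -0.83. Infiltrating myeloid and perivascular macrophage genes were higher in 14 of 17 cases by 0.57 without a call (camera adjusted p = 0.0620). They were called without Cre-labelled library 1 (median 0.98, camera adjusted p = 0.000121) and GFP-labelled library 2 (0.67, 0.0348), and the median was 0.18 without Cre-labelled library 3 and -0.36 without both kidney libraries; the neutrophil genes S100a9 and S100a8 led them with 1.11 ± 0.38 and 1.09 ± 0.37 (SE), and without both kidney libraries these were -0.11 and 0.015.

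Ribosomal protein genes were higher in 30 of 38 cases by a median of 0.086 (camera adjusted p = 0.00511; adjusted p = 0.627 with an estimated correlation), none past the list alone, and lost the call without GFP-labelled library 1 (0.285) or Cre-labelled library 1 (0.0536), with medians of 0.045 and 0.083. The median was 0.16 without GFP-labelled library 3, and with the GC and length trend removed it was 0.017 (camera adjusted p = 0.398). Rpl5 and Rpl23 led them with log2 differences of 0.25 ± 0.055 and 0.27 ± 0.081 (SE). Nuclear-encoded respiratory chain genes, led by Atp5c1 and Cox6c (0.20 ± 0.061 and 0.30 ± 0.098), and mitochondrially encoded genes, led by mt-Nd3 and mt-Co3 (0.29 ± 0.083 and 0.28 ± 0.085), gave no call, with medians of 0.041 and 0.056 (camera adjusted p = 0.0896 and 0.0673). They passed in 10 and 14 of 25 refits. Respiratory chain genes had a median of 0.079 without GFP-labelled library 3 and 0.019 without GFP-labelled library 1 (camera adjusted p = 0.00947 and 0.554), and mitochondrially encoded genes 0.13 without Cre-labelled library 1, 0.11 without GFP-labelled library 1 and 0.011 without Cre-labelled library 2 (camera adjusted p = 0.00232, 0.0409 and 0.444). No call was given either by the endoplasmic reticulum and ATF4 stress list, with a median of 0.11 (camera adjusted p = 0.592) that was 0.012 without Cre-labelled library 3 and 0.071 without GFP-labelled library 1, and Asns and Vldlr as leading genes (-0.40 ± 0.082 and -0.27 ± 0.059), or the cell division list, with a median of -0.0072 and a mean of -0.19 against camera's upward direction (camera adjusted p = 0.462) and Pcna and Mcm5 as leading genes (0.38 ± 0.089 and 0.74 ± 0.24). Without GFP-labelled library 1, which holds testis transcripts, the cell division median was 0.41 and the list was called (camera adjusted p = 0.000608). The sex-linked list had too few tested genes. Of 307 KEGG pathways, camera called 60 with the preset correlation, 35 higher and 25 lower, and 0 with an estimated one, where 12 had an unadjusted p under 0.05. Pathways for the glutamatergic synapse and for steroid biosynthesis were lower, with medians of -0.10 and -0.19 (camera adjusted p = 0.00530 and 0.00367; adjusted p = 0.750 with an estimated correlation for each). The related pathways for the synaptic vesicle cycle and terpenoid backbone biosynthesis gave no call (camera adjusted p = 0.0896 and 0.109). The smallest p belonged to the pathway named Staphylococcus aureus infection, higher by a median of 0.47 (camera adjusted p = 4.22e-05). This pathway test was added after seeing the data.

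With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled split called 2 genes and the highest of the other splits 0; it had 3593 genes at an unadjusted p under 0.05 against at most 1331; and it called 23 lists against at most 16. In each case 1 split, the labelled one, reached its count.

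The first pattern weighed is that Ruvbl2 was not lower in the Cre-labelled libraries. Scaling between libraries hiding a fall was examined with other fits. Over 13 alternative fits the lowest log2 difference was 0.044, above the -0.3 set beforehand as the size of a hidden fall. Several of these fits share a scaling and differ only in filter, pseudocount, moderation or weights. Across them the median log2 difference of all tested genes moved only between -0.045 and 0.023, which left little room to reach -0.3. No fall was seen under the scalings tried, but an error common to all of them would not show, so scaling is not excluded. It also stays open that recombined cells, or the deleted exons, may be too small a part of the gene-wide count. The lower 95% bound of -0.18 leaves room for a diluted loss. Mislabelled columns were not tested.

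The second pattern is the lower level of neuronal and synaptic genes, whose 174 pooled genes differed by -0.20 ± 0.040 in mean log2 (SE over libraries). Length or GC bias is argued against as the whole cause, since the difference was -0.18 ± 0.028 after each library's GC and length trend was removed. A smaller share of neurons in the dissected tissue would raise all other cell types alike, while ependymal genes exceeded oligodendrocyte genes by 0.45 ± 0.26 and homeostatic microglia genes exceeded oligodendrocyte precursor genes by 0.21 ± 0.090 (SE). Of 15 such pairs 5 differed by more than 2 SE, against up to 6 in other splits of the libraries, so that share stays open, as does a change in microglia or ependymal cells. Library quality cannot be told apart from the labels, because the lowest Cre-labelled level of the ribosomal RNA model was 3.29 times the highest GFP-labelled level, and loss of RUVBL2 in the infected neurons stays open, untested, since the targeted gene was not lower.

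The third pattern is the kidney transcripts of Cre-labelled libraries 2 and 3. RNA or reads from kidney is a candidate source: of 30 kidney genes, 1 of them (Slc22a6) also in the mural list, 28 (93.3%) were higher in both libraries than in each of the other 4. Kap, an abundant kidney transcript, reached 179.5 and 190.03 CPM there, against 5.13 to 20.4 CPM elsewhere. A response of the PVH to Cre is argued against, because Cre-labelled library 1 differed from the GFP-labelled libraries by a median log2 of -0.31, where libraries 2 and 3 differed by 3.48. The step at which such RNA or reads entered was not tested.

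Hnrnpa3 stood at 5.90, 5.39 and 7.77 CPM in the Cre-labelled libraries and at 165, 157 and 148 CPM in the GFP-labelled ones, while Gm5641, whose sequence shares 100% of its 31-base words with Hnrnpa3, stood between 56.5 and 69.3 CPM in all 6. Rps27rt stood at 4.88 ± 3.00 and 33.5 ± 7.54 CPM (SD, n = 3). Oxt ranged from 34.9 to 364 CPM and the thalamic marker Tcf7l2 from 32.4 to 161 CPM over the 6 libraries.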
